A study of Mus musculus with 56 samples.

How the data were processed

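Gene expression was measured on 1-colour oligonucleotide arrays in prefrontal cortex (29 arrays) and nucleus accumbens (27 arrays) of inbred mice. Per the labels, each array held RNA of 3 pooled male mice of 1 strain. The values used were the authors' deposited probe set intensity values, on a linear scale. GCRMA, which corrects background, quantile-normalizes and summarises probes, is named in the submitters' processing notes, and its version is not given in the sources used here. Scanner files were not used here. By the values, each region was normalized in its own run: the value at rank 11 from the bottom lay between 0.985 and 1.02 log2 units on cortex arrays and between 1.12 and 1.15 on accumbens arrays, and the value at rank 116 from the top between 12.26 and 12.36 and between 12.40 and 12.51. Bright values were exactly equal in 5151 of 6566218 comparisons between arrays of 1 region and in 31 of 6791742 between regions.

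The table held 45015 probe sets, 64 of them controls, which were left out. In the platform's gene table, 34880 probe sets had 1 gene symbol, 923 had several and 9148 had none, and none was named from a probe set with several. Of the symbols, 34690 were looked up by their gene identifier and 0 changed. No genome was used, so no coordinates are given.

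Intensities were turned to log2 with no pseudocount. A probe set was kept if it was above log2 5 on at least 13 of the 54 paired arrays, and a gene was represented by its brightest kept probe set, which left 10684 features. Probe sets of a gene can disagree, as reported. The number of arrays limits the precision, and 1 array per strain and region leaves the spread of strain by region as the error.

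Both regions of a strain came from the same brains, per the design text, so strain was a block in the model: limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with a region coefficient and strain coefficients on 54 arrays of 27 strains. Region was tested by the moderated t and strain by the moderated F test, with Benjamini-Hochberg adjustment and a threshold of 0.05. The pairing was checked by matching: 24 of 27 cortex arrays correlated best with their own strain's accumbens array. Of the 21 gene lists, 20 had tested members. They were tested with camera (correlation 0.01, and an estimated correlation beside it), fry, and a one-sided Fisher's exact test of strain-dependent members.

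Single-strain genes, strain matching, similarity of related strains, probe set agreement and the region score of each array were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Permutation tests used 100000 draws, and shuffles and refits 100. The named genes were chosen by a fixed rule: the 12 with the largest region difference in each direction among those past the threshold with the same sign in all 27 strains, the 20 with the largest SD of strain means, the 10 with the largest single-strain gap, up to 4 per list by size and up to 2 against the list median, and all measured genes with known strain variants. The text names part of the list genes.

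Simulated data tested the region and strain tests, strain matching, the single-strain count and the position measure, with features drawn independently. The region and strain simulation used the real feature means and residual spread on 10684 features. The matching and single-strain simulation gave every feature the same median spread. The position simulation used a set noise level and scored 1027 to 1042 features. Gene list tests, related strains, probe set agreement and dissection shares were not simulated. For the region difference, 72% of features changed by log2 0.25 were called and 100% of those changed by 0.5, 1 or 2, with 0.15% of unchanged features called. For the strain difference, 68%, 94%, 98% and 100% were called at SDs of strain means of 0.25, 0.5, 1 and 2, with 0.2% of unchanged features. Strain matching recovered 27 of 27 simulated strains and 1 after shuffling, and the single-strain count recovered 100 of 100 planted features with 0 of 9584 others. In simulated mixtures, arrays with a share of 0, 0.5 and 1 of another strain had median positions of 0.021, 0.489 and 0.984. The simulated reference and partner arrays were pure and the features were not selected by a strain test. The real positions rest on 88 to 98 selected features. The simulation therefore does not cover a doubtful zero point or a mixture in both arrays of a pair.

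Alternatives were no filter or a filter at log2 7, quantile normalization again, centring, every probe set, leaving out probe sets prone to cross-hybridisation, trend and robust variance, the oligodendrocyte list as a covariate, no replicate block, a threshold of 0.01, and leaving out strains. A fold against a region mean below log2 5 was given as a lower bound from the other region's mean and log2 5. Spans between strains that began below log2 5 were bounded in the same way. Leaving out C57BR/cdJ and C58/J together, or the 5 strains whose arrays stood apart in striatal genes, or these and 4 strains with raised cortical genes in accumbens, and raising values under log2 5 to it, were chosen after seeing the data.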

Results

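The data were gene expression microarrays of 2 brain regions of inbred mice. Prefrontal cortex, a region of executive control, was profiled in 29 strains with 29 arrays, and nucleus accumbens, the ventral part of the striatum, in 27 of them with 27 arrays. Each of the 56 arrays was hybridised with RNA pooled from 3 male mice of 1 strain, 8 to 10 weeks old, and both regions of a strain were taken from neighbouring slices of the same brains. MRL/MpJ and NZO/HILtJ were profiled in cortex only, so 54 arrays of 27 strains entered the paired comparisons. The median probe set intensity lay between 9.94 and 10.43 in cortex arrays and between 9.66 and 10.14 in accumbens arrays, and the number of arrays limits the precision of every estimate. With 1 pool per strain and region, n below is the number of strains, and the spread between strains includes the spread between pools.

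The first comparison asked which genes differed between the 2 regions. Genes of striatal projection neurons were far brighter in the accumbens. Gpr6, an orphan receptor of striatal neurons, rose from 3.11 ± 1.24 in cortex to 10.32 ± 0.90 in accumbens (log2 intensity, mean ± SD, n = 27), a log2 difference of 7.21 (SE 0.28). Where a region's mean was below log2 5, the level of the filter on dim probe sets, the fold is a lower bound against that level, a choice made after seeing the data. So bounded, Gpr6 was at least 40.1-fold higher, Cartpt, which encodes the neuropeptide precursor of CART, at least 15.7-fold, and Dlk1, a membrane protein related to Notch ligands, at least 16-fold. The dopamine D2 receptor gene Drd2 was at least 10.8-fold higher, the retinoic acid receptor gene Rarb at least 12.3-fold, and Rgs9, a regulator of G protein signalling, at least 26.2-fold. Nts, the neurotensin precursor gene, was at least 8.12-fold higher, and the opioid precursor gene Penk, measured well in both regions, was 33.2-fold higher (log2 difference 5.05, SE 0.20). Lrrc10b, Six3, Slc35d3 and Pbx3 were at least 5.70-, 10.9-, 11- and 21.2-fold higher. These 12 had the largest measured differences among genes past the threshold with the same sign in all 27 strains, which was the condition for naming them, and their limma adjusted p values ran from 2.6e-32 for Dlk1 to 1.3e-16 for Lrrc10b.

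Genes of cortical neurons changed in the opposite direction. Nrn1, which encodes the neurite growth factor neuritin, was at 10.14 ± 0.29 in cortex and 3.58 ± 1.00 in accumbens (n = 27), at least 35.3-fold lower. Slc17a7, the vesicular glutamate transporter gene of cortical neurons, was at least 34.3-fold lower, and the transcription factor gene Neurod6 at least 18.6-fold. The neuropeptide gene Cck, above log2 5 in both regions, fell by 6.07 on the log2 scale (SE 0.19), the neuropeptide gene Vip was at least 14.3-fold lower and the neurotrophin gene Bdnf at least 5.66-fold. Zbtb16, Rtn4rl2, Nwd2, Fezf2 and Prss12 were at least 10.1-, 4.62-, 4.96-, 6.84- and 5.68-fold lower, and C1ql3, whose accumbens mean lay at 5.01, was 48-fold lower. These 12 were chosen by the same condition, and their limma adjusted p values ran from 5.5e-35 for Rtn4rl2 to 3.6e-19 for Slc17a7.

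**Figure D1:**
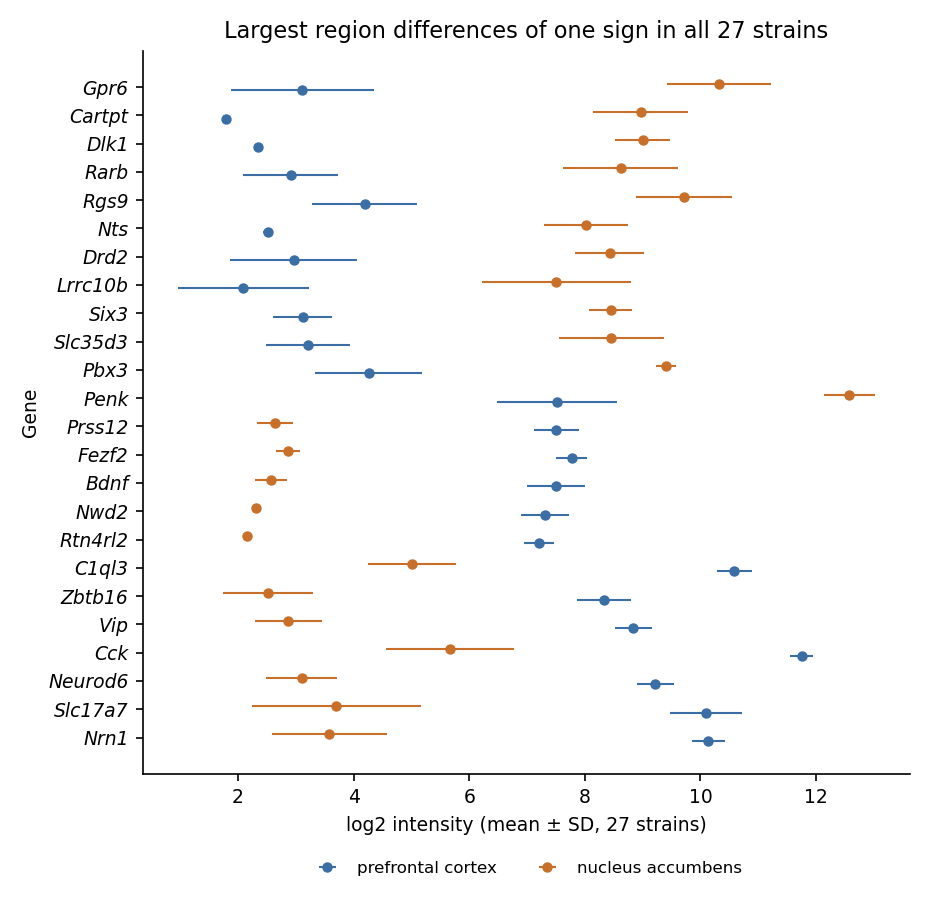
Log2 intensity (x axis) of the 12 genes with the largest region difference in each direction among those with the same sign in all 27 strains (y axis), as mean ± SD over 27 strains in prefrontal cortex and nucleus accumbens. Gpr6 is at 3.11 in cortex and 10.32 in accumbens, and Nrn1 is at 10.14 in cortex and 3.58 in accumbens.

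Of 10684 features tested (8811 named genes and 1873 probe sets without a single gene name), 5451 were higher and 3516 lower in the accumbens at an adjusted p under 0.05 (limma). At a difference of at least 2-fold, 886 were higher and 757 lower, or 646 and 555 with region means under log2 5 raised to that level. By the values, the arrays of the 2 regions were normalized in separate runs, so region and normalization run cannot be told apart, and the median feature was 0.12 log2 units higher in the accumbens. The differences given here include that shift unless another scaling is named. After quantile normalization across all arrays the split was 4408 higher and 4426 lower (726 and 916 at 2-fold), after centring each array it was 4563 and 4257 (756 and 871 at 2-fold), and with no filter it was 10293 and 12391. The 3' end of actin was brighter than its 5' end by 1.74 ± 0.27 log2 units in cortex and 1.92 ± 0.18 in accumbens (n = 27), a difference of 0.17 (two-sided permutation test, p = 0.0022; larger in accumbens in 19 of 27 strains). This sign of RNA quality thus moved with region beside all gene groups described next, whereas the same measure for Gapdh differed by 0.03 (p = 0.36).

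Among the gene lists fixed before the data were examined, all 25 measured genes of medium spiny neurons, the projection neurons of the striatum, rose in the accumbens, with a median log2 difference of 4.28 (3.43 with region means under log2 5 raised to it). Drd1, the dopamine D1 receptor gene, was 25-fold higher (log2 difference 4.65, SE 0.20), and the retinoid receptor gene Rxrg was at least 5.79-fold higher. The list passed the camera test (adjusted p = 7.81e-09) but not with its estimated correlation (adjusted p = 0.493 with an estimated correlation). Of 19 cortical excitatory neuron genes, 18 fell and 1 rose, with a median of -2.91 (-1.89 with that floor). Fezf2, a transcription factor of deep cortical layers, was among those that fell, and Tle4, a corepressor of layer VI neurons, was the gene that rose, by 1.45. This list passed camera (adjusted p = 1.01e-09) and kept its call with an estimated correlation (adjusted p = 0.0247). Adjusted over the list alone, the counts past the threshold were the same 25 and 19.

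All 13 myelin and oligodendrocyte genes rose, with a median of 1.20 (camera adjusted p = 0.00788; adjusted p = 0.596 with an estimated correlation). Mobp, a myelin component, was 3.95-fold higher, Mal 3.30-fold and Mog 2.93-fold. All 12 immediate early genes, which neurons induce on activity, fell, with a median of -1.40, or -1.23 with the floor (camera adjusted p = 3.57e-05; adjusted p = 0.493 with an estimated correlation). Arc was 4.85-fold lower and Fos 4.10-fold, both above log2 5 in both regions, and Ier2, dim in accumbens, was at least 1.54-fold lower. Adjusted over the list alone, 13 and 12 genes passed. After quantile normalization the spiny neuron, cortical neuron, oligodendrocyte and immediate early lists held the same counts of higher and lower genes.

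The other lists held genes that moved both ways and did not pass camera. Of 15 interneuron genes, 8 rose and 6 fell (adjusted p = 0.935), with a median of 0.67 and a mean of -0.02. Slc32a1 and Gad2, which serve the release and synthesis of GABA, were 5.57- and 5.43-fold higher, and Pvalb, a calcium-binding protein of fast-spiking cells, was at least 12.6-fold lower. Of 11 monoamine genes, 7 rose and 4 fell (adjusted p = 0.239): the serotonin receptor genes Htr2c and Htr1b were 22.1-fold and at least 11-fold higher, and Htr1a was at 4.95 in cortex and 3.02 in accumbens, both dim. Of 25 neuropeptide and receptor genes, 13 rose and 12 fell (adjusted p = 0.717, direction down, against a median of 0.27 and a mean of 0.36). Among 18 glutamate receptor genes, 7 rose and 6 fell (adjusted p = 0.957): the presynaptic receptor gene Grm2 was at least 4.29-fold lower and the kainate receptor gene Grik2 was 5.40-fold higher. That list's median of 0.04 changed sign to -0.06 after quantile normalization. Adjusted over the list alone, 14, 11, 25 and 13 genes of these lists passed.

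Of 10 GABA receptor genes, 8 rose and 2 fell (adjusted p = 0.309), with Gabrg1 5.06-fold higher. Of 10 retinoic acid genes, 7 rose and 2 fell (adjusted p = 0.309): Rxrg rose, and Aldh1a2, a retinoic acid synthesis gene, was at least 1.52-fold lower. Of 18 stress and trophic genes, 7 rose and 9 fell (adjusted p = 0.256), Crhbp being at least 3.05-fold lower and Crh, which encodes corticotropin-releasing hormone, 2.35-fold higher. Microglial genes were 8 higher and 1 lower of 11 (adjusted p = 0.239), and astrocyte genes 5 higher and 5 lower of 14 (adjusted p = 0.537), with Gfap falling by 1.55. Endothelial and mural genes were 3 higher and 8 lower of 11 (adjusted p = 0.117), antigen presentation genes 2 higher and 6 lower of 8 (adjusted p = 0.239), and oxidative phosphorylation genes 14 higher and 8 lower of 27 (adjusted p = 0.957), with a median of 0.11. After quantile normalization oxidative phosphorylation genes were 12 higher and 11 lower with a median of 0.03, and endothelial genes 1 higher and 8 lower. Septal and ventral forebrain genes were 5 higher and 2 lower of 8 (adjusted p = 0.309), olfactory and neuroblast genes 2 higher and 1 lower of 4 (adjusted p = 0.957), and genes with known strain variants 5 higher and 3 lower of 8 (adjusted p = 0.957, direction down, with a median of 0.25 and a mean of -0.01). Choroid plexus genes were 3 higher and 2 lower of 5 (adjusted p = 0.957, direction down, against a median of 0.38 and a mean of 0.37): Clic6, a chloride channel protein, was at least 3.85-fold higher and Igfbp2 at least 4.79-fold lower. Adjusted over the list alone, each of these 12 lists had as many genes past the threshold as it had higher and lower genes together. None of the blood genes was bright enough to be tested.

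The spiny neuron list mean minus the cortical neuron list mean separated the regions on every array. It lay between 2.26 and 5.11 in accumbens arrays and between -3.05 and 1.15 in cortex arrays. The MA/MyJ cortex array was the highest cortex array, with the next at -2.58, and the BALB/cByJ accumbens array was the lowest accumbens array. The CE/J, NON/LtJ and WSB/EiJ accumbens arrays were low in striatal genes too. Without these 5 strains, 5421 features were higher and 3609 lower, and the same 4 lists passed camera. The NOD/LtJ accumbens array, with a score of 3.66, below the 3.96 of WSB/EiJ, had the highest cortical neuron list mean of the accumbens arrays, at 6.04, followed by SJL/J at 5.83, P/J at 5.70 and BUB/BnJ at 5.69. Without these 4 strains as well, 5301 features were higher and 3511 lower, and the same 4 lists passed. Both choices were made after seeing the data.

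**Figure D2:**
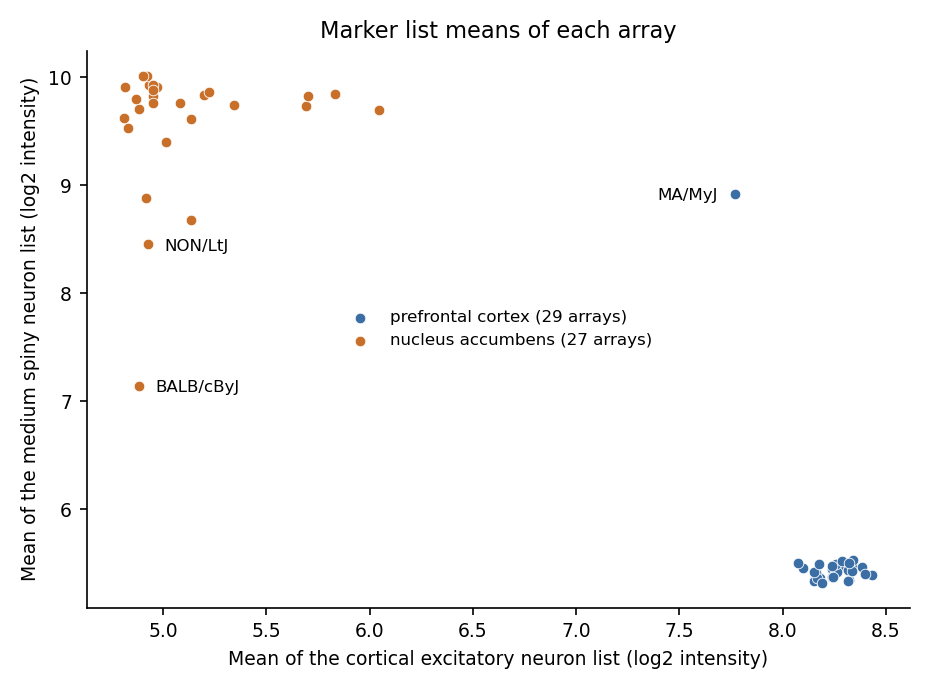
Mean log2 intensity of the cortical excitatory neuron list (x axis) and of the medium spiny neuron list (y axis), with 1 point per array, 29 prefrontal cortex and 27 nucleus accumbens. The MA/MyJ cortex array lies apart from the other cortex arrays, and the BALB/cByJ accumbens array is lowest on the y axis among the accumbens arrays.

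The second comparison asked which genes differed between the 27 strains in both regions. Of the 20 most variable genes, 19 had their lowest strain mean below log2 5, and Pisd-ps3 was above it in every strain (7.11 to 11.58). Rpn1, a subunit of the complex that attaches glycans to new proteins, averaged 2.33 in P/J and 2.43 in CE/J against a strain median of 9.87 (limma adjusted p = 8.0e-28). Rpn1, H2-D1, H2-K1, Erdr1, Phgdh and Pisd-ps3 were measured on probe sets of a type prone to cross-hybridisation. Whether a low value there means low RNA was not tested. Gm13306 ranged from 3.30 in SM/J to 11.59 in BUB/BnJ. The class I histocompatibility genes H2-D1 and H2-K1, known to vary between strains, reached 8.82 and 7.93 in their highest strains, at least 3.82 and 2.93 log2 units above the lowest, and Serpina3n, a protease inhibitor of reactive astrocytes, was at least 2.44 higher in BTBR T+ tf/J than in MA/MyJ. As for the regions, a span from a strain mean below log2 5 is a lower bound against that level. Slc8a1, a sodium-calcium exchanger gene, was lowest in CE/J at 2.79 against a median of 7.62, and Galc, a lysosomal enzyme of myelin lipid turnover, was lowest in NZW/LacJ at 2.50 against 5.92. Rpgrip1 was highest in C57BL/6J at 8.75 against a median of 4.55. Cap1, Soga3, Tmem267, Stk25, Erdr1, Phgdh, Reep3, Pdxdc1, Pnma2, Pisd-ps3, Zfp945 and 4933431E20Rik completed the 20 most variable genes, with SDs of strain means from 1.73 for Cap1 to 1.27 for 4933431E20Rik. With strain means under log2 5 raised to it, 13 of the 20 stayed among the 20 most variable.

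In all, 2180 features, 1702 of them named genes, passed the strain test at an adjusted p under 0.05 (moderated F, 26 and 26 degrees of freedom before moderation). The strain means of 1363 of them spanned at least 1 log2 unit, and of 1126 with that floor. Over all features the median SD of strain means was 0.18 and the median residual SD 0.20, and the median share of variance between strains common to both regions was 0.209. An effect of strain cannot be separated from an effect of the pool of mice that stood for it.

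Of 8 measured genes listed as having known strain variants, 5 passed. Glo1, an enzyme that detoxifies methylglyoxal, ranged from 8.59 in PL/J to 10.97 in BALB/cByJ (adjusted p = 5.4e-14). Kcnj9, a potassium channel subunit gene, ranged from 6.06 in MA/MyJ to 8.87 in SWR/J (adjusted p = 1.4e-08), and Alad, a haem synthesis gene, from 5.66 in WSB/EiJ to 8.16 in BALB/cByJ (adjusted p = 2.7e-10). Wdfy1 was lowest in C57BL/6J at 5.11, with the next strain at 7.25 (adjusted p = 3.0e-07), and the GABA receptor gene Gabra2 was also lowest in C57BL/6J, at 7.54 against a median of 8.67 (adjusted p = 0.0074). Nnt (adjusted p = 0.054), H2-Ea (0.058) and Ide (0.84) did not pass, with ranges of 1.12, 1.20 and 0.43 log2 units.

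**Figure D3:**
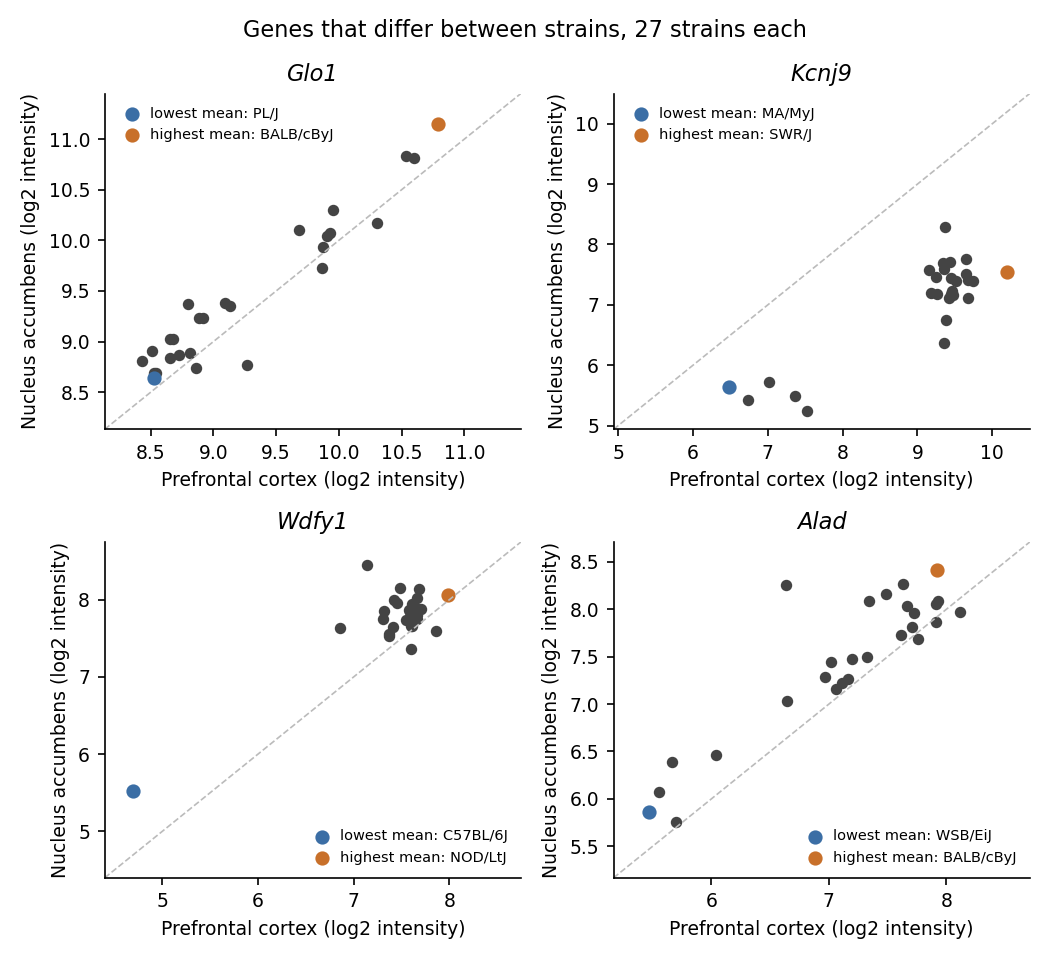
Log2 intensity in prefrontal cortex (x axis) and nucleus accumbens (y axis) of 4 genes with known strain variants, with 1 point per strain and 27 strains in each panel. The dashed line marks equal values, and coloured points mark the strains with the lowest and highest mean, such as C57BL/6J for Wdfy1 at 5.11.

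Microglial genes were the list most often strain-dependent, with 8 of 11 passing (one-sided Fisher's exact test, adjusted p = 0.00378; 10 adjusted over the list alone). That test takes genes as independent, but genes of 1 cell type can vary together (estimated correlation 0.257 in this list), so its p value may be too small. The complement gene C1qb, on a probe set prone to cross-hybridisation, spanned 1.89 log2 units and the protease gene Ctss 1.22. By contrast C1qc, below log2 5 in most strains (median 4.52), was at least 1.06 higher in P/J than in CBA/J. Endothelial genes (6 of 11), antigen presentation genes (5 of 8) and the genes with known variants each reached an adjusted p of 0.0512, and immediate early genes (6 of 12) reached 0.0687, each of these lists with 7 adjusted over the list alone. Among the latter, Fos spanned 3.21 log2 units from BTBR T+ tf/J to NON/LtJ and Npas4 at least 2.71 with PL/J highest. None of the 25 spiny neuron genes, 25 neuropeptide genes, 11 monoamine genes or 15 interneuron genes passed the strain test. Of these, 12, 14, 7 and 4 had a region mean below log2 5. The test looks for differences shared by both regions, so a strain difference in 1 region alone was not tested. The spiny neuron genes had a median SD of strain means of 0.54, against 0.18 over all features. The MA/MyJ cortex and BALB/cByJ accumbens arrays, which stood apart in striatal genes, add to the error of the test there. List members were not counted without these strains, so the absence of calls does not show an absence of strain differences. Stress and trophic genes (7 of 18) reached an adjusted p of 0.151 and GABA receptor genes (4 of 10) of 0.327, and every other list had an adjusted p of 1.

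Some genes were set apart in 1 strain. In 76 features, 52 of them named genes, 1 strain was beyond all others by at least 1 log2 unit in both regions, lowest in 63 and highest in 13. The highest count in 100 shuffles of the strain names in 1 region was 17. With values under log2 5 raised to it, 48 features remained in the count, 36 lowest and 12 highest, against at most 10 in the shuffles. Spock2, a brain proteoglycan gene, was at 4.27 in cortex and 4.92 in accumbens of I/LnJ against medians of 10.72 and 10.84 in the others, and Stard10, a lipid transfer gene, was at 2.48 in both regions of I/LnJ. Sfpq, a splicing factor gene, and Erdr1 were lowest in RIIIS/J, Sdr39u1 in NON/LtJ, 2900055J20Rik in WSB/EiJ, Prpsap2 in PL/J and Otud3 in BALB/cByJ. Stk4, a kinase of the Hippo pathway, was lowest in KK/HlJ, and the spliceosome gene Cwc22 was highest in WSB/EiJ, at 9.20 and 10.49 against 5.58 and 6.24. The other probe set of Sfpq also placed RIIIS/J lowest, but only at -0.341 log2 units from the median of the others in cortex and -0.744 in accumbens. The named probe set was at 3.02 against 9.01 and at 4.24 against 10.08, so the size of that difference was not shared. Those of Stk4 and Sdr39u1 did not place the same strain lowest in both regions. KK/HlJ had 11 such features, WSB/EiJ 9, RIIIS/J 8, and I/LnJ and SM/J 7 each.

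Strain profiles were compared between regions as a check of the labels. For 24 of 27 strains, the cortex array correlated best, across features, with the accumbens array of its own strain (p = 1e-05, the smallest that 100000 permutations can give), and 25 accumbens arrays matched their own strain's cortex array best. The accumbens arrays labelled C3H/HeJ and C57BR/cdJ matched the MA/MyJ cortex array best (0.285 and 0.162), which stood apart in striatal genes. With every probe set, 21 cortex and 25 accumbens arrays matched their own strain best. The cortex array of C3H/HeJ correlated best with the accumbens array of CBA/J, the array labelled C57BR/cdJ with that of BTBR T+ tf/J (0.371 against 0.146 for its own strain), and the array labelled C58/J with that of DBA/2J (0.305 against 0.256). Features are not independent replicates. Without C57BR/cdJ and C58/J, a choice made after seeing the data, 2142 features passed the strain test.

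**Figure D4:**
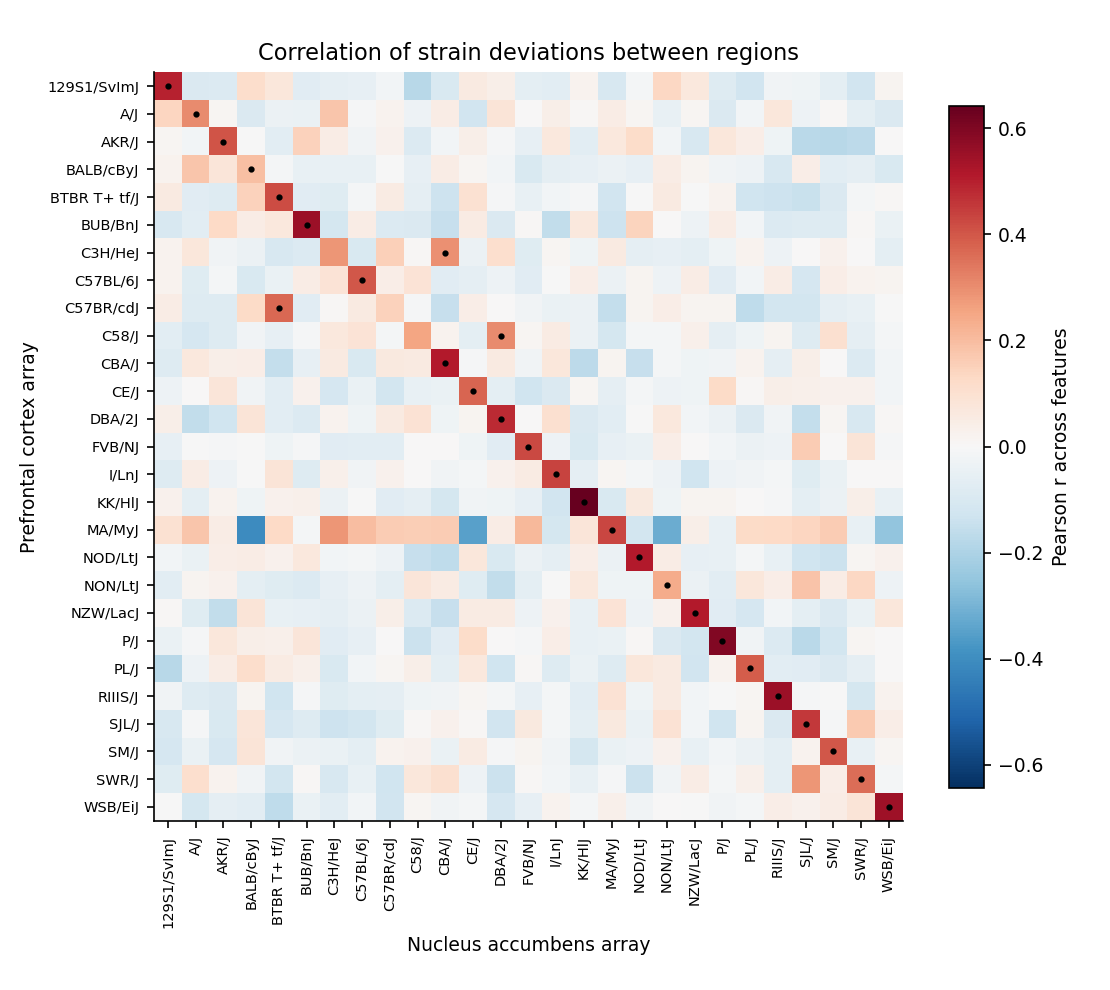
Pearson correlation across features (colour) between the deviations of each prefrontal cortex array (y axis) and each nucleus accumbens array (x axis) from their region's mean, for 27 strains. Black points mark the best accumbens array for each cortex array, which was that of its own strain for 24 of 27.

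Strains of shared ancestry had similar profiles. Over 9 such pairs, strain means correlated at a mean of 0.134 across features, against -0.036 for permuted names (one-sided permutation p = 0.00015), and without the pairs of C57BR/cdJ and C58/J the mean was 0.120 (p = 0.00285). Over the 2180 strain-dependent features alone, the mean of the 9 pairs was 0.216, against -0.037 for permuted names. On these selected features C3H/HeJ and CBA/J correlated at 0.42, the second highest of 351 pairs, and SWR/J and SJL/J at 0.343. NOD/LtJ and NON/LtJ correlated at 0.005 on the same features, rank 98.

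The agreement of 2 probe sets of 1 gene bears on sequence variants under the probes. Of 679 strain-dependent genes with another probe set, the strain means of both correlated above 0.5 in 53.8%, against 45.2% of 2788 other genes (two-sided Fisher's exact test, p = 6.58e-05). Above 0.3 the shares were 68.0% and 66.0% (p = 0.319), and below 0 they were 17.5% and 10.7% (119 of 679 against 297 of 2788, p = 2.56e-06), so strain-dependent genes held more of both high and negative correlations. The median correlation of the 679 was 0.552.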

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

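The 3 features below were named after their values had been seen, and the comparison with the other strains was also chosen afterwards. MRL/MpJ and NZO/HILtJ, profiled in cortex only, stood outside the comparisons between regions and strains. Nudcd1 was higher in the NZO/HILtJ cortex array than in any other cortex array, by 1.41 log2 units over the nearest. Pam, an enzyme gene of peptide amidation, was highest in the MRL/MpJ cortex array by 1.08 log2 units, and an unnamed probe set was lowest there by 1.24, at a level of 4.11, below log2 5. By the same criterion in cortex alone, the other 27 strains held between 0 and 132 such features, with a median of 4 and a second highest count of 20. No second region exists in these comparisons for either strain, and no explanation was tested.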

How the results depend on the processing

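Leaving out C57BR/cdJ and C58/J, or the 5 strains whose arrays stood apart in striatal genes, or these and 4 with raised cortical genes in accumbens, and raising values under log2 5 to it, were chosen after the results were seen. No named gene reversed its direction past the threshold, but the split of region calls turned with no filter (10293 higher, 12391 lower) and with quantile normalization (4408 and 4426; 726 and 916 at 2-fold), and the glutamate receptor median changed sign (-0.06). The 8967 features past the region threshold became 22684 with no filter and 5108 with a filter at log2 7 (more and fewer features tested), and 1643 at 2-fold. With the oligodendrocyte list as a covariate they fell to 6607 of 10671 tested (4064 higher, 2543 lower). The region difference of at least 2-fold became 852 at log2 7, 2496 with every probe set, and 1201 with that floor. The 2180 strain-dependent features became 1220 at log2 7, 1256 at a threshold of 0.01 1363 with a range of 1 log2 unit and 1126 with that range and floor. With an estimated correlation 1 region list passed, at adjusted p = 0.493 for spiny neuron, 0.596 for oligodendrocyte and 0.493 for immediate early genes, and with fry 18 did, since fry does not compare a list with other genes. Strain lists past the threshold rose from 1 to 2 with no filter (known variants, adjusted p = 0.0281) and 2 at log2 7 (endothelial genes, adjusted p = 0.0435). Single-strain features were 172 at a gap of 0.5, 25 at a gap of 2 and 48 with values raised to log2 5. At a correlation above 0.3 the probe set agreement was 68.0% against 66.0% (p = 0.319); the cause was not tested. Without the pairing (no replicate block), 8603 features passed region with 54 arrays and 8633 with 56. Leaving out 1 strain gave 8888 (without PL/J) to 9062 (without BALB/cByJ) region features, 1628 to 1682 at 2-fold, and 1951 (without WSB/EiJ) to 2388 (without BALB/cByJ) strain-dependent features. For the 98 genes named for region, 1328 values kept direction and side of the threshold and 14 lost the call; for the 70 named for strain, 768 kept it, 42 lost it and 7 gained it, leaving out of 1 strain not counted. Leaving out 1 strain at a time, 2646 region values kept it, and of the strain values 1823 kept it, 55 lost it and 12 gained it. Dim probe sets near background limit both comparisons.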

Other observations

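The tests of array identity and of dissection below, their bounds, and the basal forebrain list were chosen only after the results were seen, as were the correlations of list means; the tests of regrouping, probe sequence and tissue composition were set beforehand. The means of some gene lists varied between strains in both regions together. Such a mean can rest on few members. In the antigen presentation list H2-D1 and H2-K1, both on probe sets prone to cross-hybridisation, had SDs of strain means of 1.63 and 1.39. The median over that list was 0.28. Of 18 glutamate receptor genes, 2 passed the strain test. Over 27 strains, the mean of the antigen presentation list in cortex correlated with that in accumbens at r = 0.854 (Spearman's rho 0.857, permutation p = 1e-05 for both, the smallest possible; adjusted p = 0.0001 over 20 lists), at 0.842 without AKR/J and C3H/HeJ, the strains farthest from the median in cortex, and at 0.812 without WSB/EiJ and BUB/BnJ, the farthest in accumbens. The list of genes with known strain variants correlated at r = 0.941 (rho 0.890, permutation p = 1e-05 and adjusted p = 0.0001 for both) and at 0.850 without C57BL/6J and BTBR T+ tf/J, the farthest in both regions. The microglial list correlated at r = 0.651 (permutation p = 0.00039, adjusted p = 0.0019; rho 0.573, permutation p = 0.0021, adjusted p = 0.014) at 0.536 without CBA/J and WSB/EiJ, the farthest in cortex, and at 0.534 without PL/J and CBA/J, the farthest in accumbens. The glutamate receptor list correlated at r = 0.688 (permutation p = 0.00033, adjusted p = 0.0019; rho 0.519, permutation p = 0.0062, adjusted p = 0.031), but rests on RIIIS/J and WSB/EiJ, the farthest in both regions, without which r was 0.388 (permutation p = 0.055). These 4 of 20 lists passed after adjustment by r, and also by rho. The stress and trophic list, described below, passed by rho only (rho 0.504, permutation test, adjusted p = 0.032). Without C57BR/cdJ and C58/J, whose arrays are in question below, the same 4 passed (r = 0.882, 0.970, 0.657 and 0.704), and the endothelial list passed as well, at r = 0.531 (permutation p = 0.0058, adjusted p = 0.023). With all 27 strains that list reached r = 0.314 (permutation p = 0.11, adjusted p = 0.28; rho 0.267, permutation p = 0.18, adjusted p = 0.39), and r = 0.114 without I/LnJ and BTBR T+ tf/J, the farthest in cortex.

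Immediate early genes reached r = 0.458 (permutation p = 0.017, adjusted p = 0.056; rho 0.448, permutation p = 0.021, adjusted p = 0.069), with PL/J highest in cortex, r = 0.347 without PL/J and NON/LtJ, the farthest in cortex, and r = 0.307 without BALB/cByJ and PL/J, the farthest in accumbens. Stress and trophic genes reached r = 0.468 (permutation p = 0.014, adjusted p = 0.056; rho 0.504, permutation p = 0.0079, adjusted p = 0.032), r = 0.497 without I/LnJ and SM/J, the farthest in cortex, and r = 0.496 without NOD/LtJ and NON/LtJ, the farthest in accumbens. The spiny neuron list (r = 0.040, permutation p = 0.83, adjusted p = 0.88; rho -0.085, permutation p = 0.67, adjusted p = 0.75) and the oligodendrocyte list (r = 0.153, permutation p = 0.45, adjusted p = 0.82; rho 0.187, permutation p = 0.35, adjusted p = 0.64) did not pass. Without the 2 strains farthest in cortex their r was -0.241 (MA/MyJ and RIIIS/J left out) and 0.084 (129S1/SvImJ and P/J). Without the 2 farthest in accumbens it was 0.020 (BALB/cByJ and NON/LtJ) and 0.406 (MA/MyJ and NON/LtJ; permutation p = 0.042, not adjusted), so the oligodendrocyte value depends on those 2 strains. GABA receptor genes reached r = 0.292 (permutation p = 0.14, adjusted p = 0.31; rho 0.358, permutation p = 0.069, adjusted p = 0.17), r = 0.113 without AKR/J and 129S1/SvImJ, the farthest in cortex, and r = 0.502 without BALB/cByJ and P/J, the farthest in accumbens (permutation p = 0.0097, not adjusted).

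Of 100 exchanges of the region names within strains, 1, the real one, gave as many region features (8967, against 6308 at most in the others). Of 100 reassignments of the strain names in 1 region, 1, the real one, gave as many strain-dependent features (2180, against at most 30). Within the limit of 100 assignments each, this argues against a chance assignment of the names for both counts.

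The position of an array between the other region's arrays of its own strain (0) and of another strain (1) was measured over strain-dependent features. Its definition was settled after 8 had been tried, which differed in the strain test threshold, the smallest difference and a tolerance on the other strain's arrays, and the bounds for reading it were rewritten afterwards. Over the 8, the position of the cortex array labelled C57BR/cdJ toward BTBR T+ tf/J ran from 0.644 to 0.727, that of the accumbens array labelled C57BR/cdJ toward C3H/HeJ from 0.519 to 0.768, and that of the cortex array labelled C58/J toward DBA/2J from 0.379 to 0.646. They lay above 95% of the benchmark positions of 22 other strains in 7, 8 and 7 of the 8 definitions, and above every benchmark in 4, 7 and 2. The highest benchmark in cortex under the definition used was 0.44, for BALB/cByJ. Only the 4 definitions without the tolerance can test a wrong label, and a verdict below is given only where all 4 gave it.

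Shared ancestry is argued against for the cortex array labelled C58/J, since C58/J and DBA/2J hardly correlated in accumbens (r across features 0.038, against 0.616 in cortex). C57BR/cdJ correlated with BTBR T+ tf/J at 0.09 in accumbens, against 0.847 in cortex. With C3H/HeJ it correlated at -0.094 in cortex, against 0.709 in accumbens. Each of these low values uses the other array labelled C57BR/cdJ, itself in question, so they cannot decide on ancestry there. The bound for a wrong label was the position that 95% of benchmark arrays reached at their own strain. Under the definition used it was 0.853 in cortex and 0.87 in accumbens. The accumbens array labelled C57BR/cdJ (position 0.529) and the cortex array labelled C58/J (0.398) lay below this bound in 4 of 4 definitions. That argues against a wrong label for these 2 arrays. The cortex array labelled C57BR/cdJ (0.701) did so only in 3 of 4, so there a wrong label and a mixture cannot be told apart. The partner arrays of C3H/HeJ in accumbens (0.71) and DBA/2J in cortex (0.621) also lay below the bound in 4 of 4. RNA of both pools may thus be mixed in both arrays of these 2 pairs. The lowest cortex benchmark was 0.56, however, so the DBA/2J array was not below every benchmark. The BTBR T+ tf/J cortex array (0.873) lay below the bound in 0 of 4, with an interval that reached it. The zero point for C57BR/cdJ is doubtful because both its arrays are in question, and no biological explanation other than ancestry was tested.

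Strain-dependent features may reflect sequence variants under the probes rather than RNA levels. The median correlation between 2 probe sets of a strain-dependent gene was 0.552 (95% bootstrap interval 0.506 to 0.597), above the bound of 0.5 set beforehand against variants, but that bound was wrong, since genes that did not pass the strain test reached a median of 0.455 and fewer of them were negative (10.7% against 17.5%), so the test leaves variants open. Of 26 named single-strain genes with another probe set, 8 (30.8%) had the same strain outermost there, between the bounds set beforehand, which leaves variants open for these too. For probes that favour the C57BL/6J reference, the bound set beforehand was that C57BL/6J lies above the median strain most often. It was above in 39.7% of features and ranked 25 of 27. A mismatch carried by few strains would leave C57BL/6J near the median, so this measure cannot decide. WSB/EiJ was at least 1 log2 unit below the median in the most features, 109, against 46 for C57BL/6J and 25 for C57BR/cdJ. Such probes are left open. With the oligodendrocyte list as a covariate 2044 features passed against 2180 without, within the bound set beforehand against tissue composition. That list's mean hardly correlated between regions (r = 0.153), so the covariate could remove little of a strain difference shared by both. The microglial list, whose mean did correlate (r = 0.651), was not used as a covariate. Tissue composition is therefore left open. A true difference in expression between strains stays open as well.

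Arrays that stood apart in striatal genes may differ in dissection. In the MA/MyJ cortex array, 104 features high in accumbens gave an accumbens share of 24.8% (quartiles 6.05% and 50.58%) and 105 features high in cortex 35.3%. The difference of 10.5 percentage points is as striatal tissue in the sample would give. But cortex SDs over the 27 strains, MA/MyJ included, were 0.04 for Cartpt, 0.05 for Dlk1 and 0.08 for Nts, against 1.24 for Gpr6 and 1.10 for Drd2. The first 3 genes could not have risen far in that array, so the share cannot be read as one of whole accumbens tissue. An exchange with the MA/MyJ accumbens array is argued against by that array's score of 4.81. In the BALB/cByJ accumbens array the same 104 features gave 18.4% but the 105 features high in cortex gave 98.7%, so neither can be read as its share of accumbens RNA. Slc17a6, a glutamate transporter gene of subcortical neurons named after its value was seen, was there at 8.66, at least 3.66 log2 units above the median array, which lay below log2 5. A basal forebrain list (12 genes measured, 8 of them also in a fixed list, 2 above log2 5 in the median accumbens array) was highest there, by 1.231 over the median array (0.65 with levels under log2 5 raised to it), in line with tissue from around the accumbens, while cortical tissue is argued against by a cortical list mean of -0.069 relative to the median. Zic1 was at 9.72 against a median of 7.48 and Lhx6 at 8.82 against 6.03, but Chat, the cholinergic marker, was at 2.08 against 2.07, near background, and a strain difference was not tested and stays open.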
